A study of Caenorhabditis elegans with 12 samples.

How the data were processed

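RNA was sequenced from whole N2 worms and from 3 mutant strains, with 3 libraries per group. Per the labels' protocols, embryos isolated by bleaching grew for 34 h at 20 °C on bacterial lawns until the L3 stage, RNA was extracted with Trizol, and polyA-selected libraries were read as paired 150 nt reads. Per the submitters' processing notes, Bowtie2, STAR and SAMtools were used and the genome build was ce10. Their roles and versions are not given in the sources used here. Per the file headers the build is also ce10.

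The deposited values are scores, 2 per event and library, for the included and the excluded form. The authors' score is percent spliced in multiplied by 10, a reading that rests on the values, since the 2 forms sum to 1000 for alternative splice sites, and on the track lines. No alternative splice site has a percentage of exactly 0 or 100, and 41.9% of their values stand at 0.1 or 99.9. For retained introns, skipped exons, multiple skipped exons and mutually exclusive exons the 2 scores often sum to less, for a reason not given in the sources used here, and the percentage was taken as the included score over the sum of both. For alternative 5′ splice sites its percentage is the use of the downstream site, for alternative 3′ splice sites the use of the upstream site, and for retained introns the retained form. The files hold no read counts, so the depth per library and per event is unknown, no counting interval can be given, and low-depth events cannot be removed.

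Groups were taken from the genotype labels, and replicate numbers only name libraries. No 2 libraries held identical values, with at most 30.9% of events equal within a group and 26.1% between groups in either catalogue. The tests and the rule for named features were fixed before the data were examined. That plan put count models first and limma on percent spliced in where no counts were found, so limma 3.58.1 in R 4.3.3 was used, with all 12 libraries, 4 group means and default moderation. The default, the robust option, the trend option and a logit scale had each been run on these data by the time the default was kept. The logit scale and both options together are among the alternatives. Read filters could not be applied. In their place, chosen after the files were seen, an event had to be listed in all 12 libraries with an overall mean use between 2.5% and 97.5%, which left 3411 library-intron events and 1437 annotated events. An event was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested events of its catalogue and a difference of at least 10 points. Shares and directions were tested with Fisher's exact test and exact binomial tests, and distances with permutation tests of 100000 resamples (Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6, figures with matplotlib 3.10.9). The overlap expected from shared wild-type libraries came from 100 simulations of unchanged mutants.

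The fit was tested on simulated data for H765G against wild type, with 200 events moved by 15 or 30 points. Among 3411 library-intron events it recovered 46% of the shifts of 15 points and 66% of those of 30 points, and 10 of 3211 unmoved events were called, 8.2% of the calls. Among 1437 annotated events it recovered 68% and 92%, and 6 of 1237 unmoved events were called, 3.6% of the calls. A large part of real changes of this size among alternative splice sites can therefore go uncalled.

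Named features were the 12 changed 5′ splice site pairs with the largest difference and the 3 largest of each other type, for each mutant against wild type, and the 5 largest 5′ pairs between mutants, among changed events whose libraries do not overlap between the groups. Chance alone gives non-overlap at 10% of events with 3 against 3 libraries. Ranking by difference can favour events with few reads, which could not be removed. The plan asked for 1 event per gene, and 1 event per set of events that share an intron was used. The annotated catalogue holds no alternative 5′ splice sites, so the rule for other types was applied there, after the files were seen, and the text names retained introns and skipped exons from it. Named 3′ splice sites and introns in comparisons between mutants were also added then. Grouping introns by whether they share an end with a listed pair of alternative sites was added after the data were seen as well.

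The files do not pair events with genes, and the annotation at hand is of another build, so genes, coding regions and annotated splice sites are not given. Planned gene lists and 4 genes to be reported by name are therefore not reported, and gene-level junction coverage and splice site sequence were not analysed. Introns had been matched to that annotation by length, and gene names, gene-list tests and use of annotated sites were seen. That match amounted to a conversion between builds and was discarded before the text was written. No printed value depends on it. Alternatives tried were minimum differences of 5 and 20 points, a rule of at least 15 points in all 9 pairs of libraries, fits with only the libraries compared, and leaving out each library. Added after the data were seen were a logit scale, limma's robust and trend options, minimum mean uses of 0 and 5 percent, up to 1 missing library per group, a minimum mean sum of 900 for the 2 scores and 1 event per set sharing an intron.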

Results

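The series asked how SNU66, a protein of the tri-snRNP that joins the spliceosome before its activation, bears on the choice of 5′ splice sites. It measured splicing by polyA RNA sequencing of whole Caenorhabditis elegans at the L3 larval stage. There were 12 libraries in 4 groups of 3. One group was the N2 wild type, and each of the others was 1 strain labelled with 1 protein substitution. Other differences between the strains cannot be told apart from the substitution. The substitutions were M141T in SNRP-27, another tri-snRNP protein, and H765G or H765L at the same histidine of SNU-66. Each library came with scores for 2 catalogues of splicing events, 1 built from introns found in the libraries and 1 from an Ensembl annotation. The first lists 4375 pairs of alternative 5′ splice sites and 4475 pairs of alternative 3′ splice sites, at most 50 nt apart. The second lists retained introns, skipped exons, alternative first and last exons and related events. Values are the percent use of 1 of the 2 forms of an event. In the first catalogue no value was exactly 0 or 100, 41.9% of values were listed at 0.1% or 99.9%, and among tested events these were the lowest and highest values. The number of reads behind a value is unknown. Libraries listed between 8375 and 8549 events of the first catalogue. Libraries of a group correlated across these events at r of 0.963 to 0.974, and libraries of different groups at 0.945 to 0.968. Events are not independent replicates. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The files give no gene names, so events are identified by position in build ce10. A 5′ splice site is given as the first base of its intron and a 3′ splice site as the last base. An event is called changed at a limma Benjamini-Hochberg adjusted p under the threshold of 0.05 together with a difference in mean use of at least 10 percentage points.

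The SNRP-27 mutant differed from wild type at 175 of 1553 tested pairs of 5′ splice sites, and at 23 of 1858 pairs of 3′ splice sites. On chromosome V, minus strand, a pair 34 nt apart at 6607487 and 6607453 went from 87.4% ± 2.95 use of the downstream site in wild type to 17.2% ± 5.15 in the mutant (SD, n = 3 each). On chromosome III, minus strand, the downstream site of a pair 12 nt apart (8592853 and 8592841) rose from 13.1% ± 5.70 to 79.32% ± 5.03. The downstream site at 10531249 on chromosome II, 10 nt from the upstream site at 10531239, was listed at 99.9% in all 3 wild-type libraries and averaged 19.6% ± 2.79 in the mutant. The difference for the chromosome V pair had a standard error of 3.25 points (limma adjusted p = 2.33e-06).

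Other large shifts went both ways. Use of the downstream site rose from 17.7% ± 18.2 to 97.9% ± 3.55 at a pair 4 nt apart on chromosome I (5510479 and 5510475). It also rose at chromosome IV 4564320 and 4564363, at chromosome II 9655441 and 9655402, at chromosome X 4252844 and 4252856, and at chromosome V 12950710 and 12950686, by 58.3 to 80.1 points. Use of the downstream site fell from 95.7% ± 3.53 to 25.18% ± 7.14 at chromosome I 8019653 and 8019658. It fell from 91.5% ± 1.89 to 30.6% ± 6.75 at chromosome I 2217192 and 2217195, from 70.5% ± 1.28 to 11.08% ± 3.54 at chromosome IV 12280072 and 12280075, and from 65.1% ± 8.53 to 9.13% ± 5.17 at chromosome II 12026074 and 12026067. Of these 12 pairs, 8 kept their call under every alternative setting. The 4 that did not are those just named together as rising by 58.3 to 80.1 points.

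In the first catalogue, pairs of 5′ splice sites made up 88.4% of the changed events and 45.5% of those tested (odds ratio 10.1, Fisher's exact test, two-sided, p = 1.52e-38, events treated as independent). This sets 5′ pairs against 3′ pairs only, here and for H765G and H765L. In M141T 11.3% of tested 5′ pairs and 2.09% of tested introns in the annotated catalogue were called. A site used only in mutants can enter the catalogue and pass the filter on mean use because of the mutants. The tested list thus partly depends on the change itself, here and for H765G and H765L. Of the 175 changed pairs, 76 moved to the downstream and 99 to the upstream site. The downstream share of 43.4% (exact 95% interval 36 to 51.1) was close to the 43% of unchanged pairs (exact binomial p = 0.939, two-sided), and without mutant replicate 3 it was 41.6%, on the other side of the share of unchanged pairs. Among 3′ splice site pairs, use of the upstream site rose at 21 and fell at 2. This count of 23 was 38 and 47 without replicate 1 of wild type or of the mutant. It was 12 without wild-type replicate 2 or 3, and 14 without mutant replicate 2. More pairs rose than fell under every alternative setting. The lean was weaker under the rule of 15 points in all 9 pairs of libraries (6 and 4) and without wild-type replicate 2 (8 and 4). The largest were chromosome III 2825687 and 2825691, where upstream use rose from 12.95% ± 7.81 to 83.3% ± 28.8, chromosome I 8273368 and 8273377, and chromosome II 1373067 and 1373058. All 3 lost their call under at least 1 alternative setting. Few annotated events changed, 13 of 1437, among them 6 of 382 introns with a higher retained share and 2 with a lower one. The intron at chromosome IV 12280075 to 12280123, whose 5′ splice site is 1 of the pair above, went from 8.57% ± 2.03 to 44.7% ± 3.69 retained. This share counts only splicing from 12280075, whose use fell from 70.5% to 11.08%, so it could rise without more unspliced RNA. All 8 changed introns share an end with a listed pair of alternative sites, so use of another site was not separated from retention there. With only the 6 libraries of this comparison in the fit, 97 pairs of 5′ splice sites were called and their downstream share was 33% (exact binomial p = 0.0401). Without wild-type replicate 1 the odds ratio was 4.82, without mutant replicate 1 it was 4.24, and without wild-type replicate 2 it was 15.7. Without mutant replicate 2, 7 annotated events were called, 4 of them introns.

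**Figure D1:**
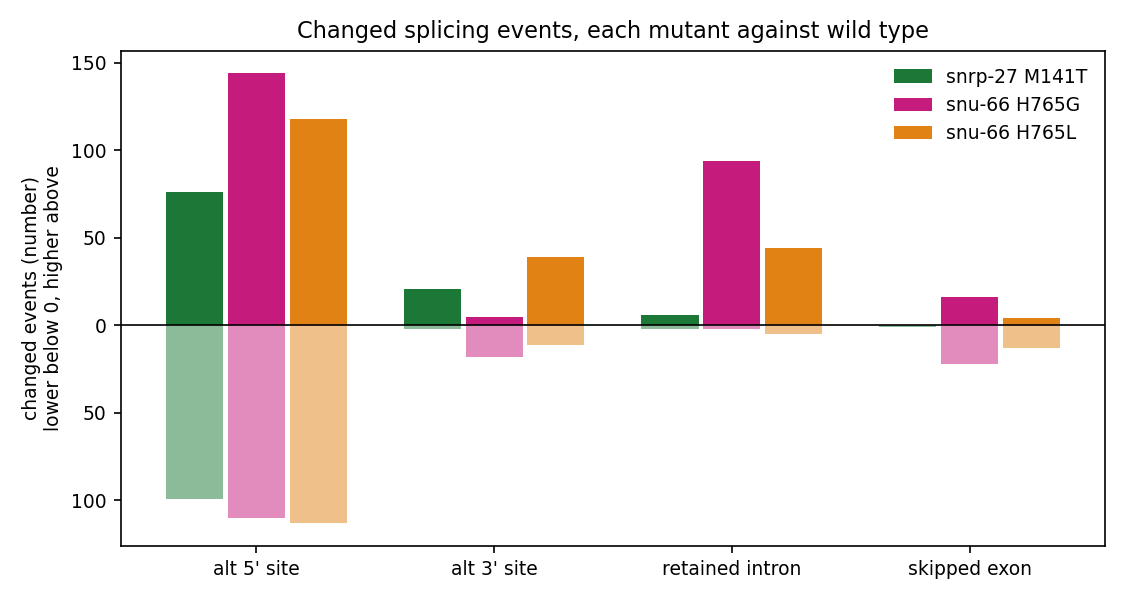
Numbers of changed events for each mutant against wild type (3 libraries each), by event type. Solid bars above 0 count events with higher use of the downstream 5′ site, the upstream 3′ site, the retained intron or the included exon, and pale bars below 0 count lower use. Changed 5′ splice site pairs number 175, 254 and 231, and the retained share is higher at 94 introns in H765G.

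The mutant with glycine in place of the SNU-66 histidine (H765G) differed from wild type at 254 of 1553 pairs of 5′ splice sites and 23 of 1858 pairs of 3′ splice sites, and the retained share was higher at 94 introns, 45 of which share an end with a listed pair of alternative sites. At the chromosome V pair 6607487 and 6607453, use of the downstream site dropped to 5.31% ± 4.74 from the wild-type 87.4% ± 2.95 (SD, n = 3 each). At a pair 5 nt apart on chromosome V, minus strand (7434825 and 7434820), it rose from 18.1% ± 4.76 to 94.5% ± 2.10. The downstream site at chromosome IV 8649186, 8 nt from 8649194, was listed at 0.1% in wild type and reached 76.5% ± 7.43. The difference at the chromosome V pair 5 nt apart was 76.4 points with a standard error of 2.57 (limma adjusted p = 3.46e-07).

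The downstream site also gained use at chromosome I 14646142 and 14646147, from 0.1% to 70.9% ± 3.19, and at chromosome III 11724141 and 11724137, from 9.39% ± 5.74 to 84.9% ± 9.04. It gained at chromosome V 19431032 and 19430990 (80.3 points), at chromosome I 5510479 and 5510475 (79.5 points), at chromosome III 8592853 and 8592841 (66.4 points) and at chromosome IV 1496351 and 1496306 (66.5 points). It lost use at chromosome IV 4758479 and 4758474, from 83.3% ± 28.8 to 0.1%, at chromosome III 8792092 and 8792125, from 90.8% ± 15.7 to 15.03% ± 13.2, and at chromosome III 10986962 and 10986929, from 75.5% ± 21.4 to 0.1%. The pairs at 10986962 and at 1496351 lost their call without several of the single libraries, and the other 10 kept it under every alternative setting.

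Pairs of 5′ splice sites made up 91.7% of the changed events in the first catalogue (odds ratio 15.6, Fisher's exact test, two-sided, p = 1.54e-64). Of the 254 pairs, 110 moved upstream and the others downstream, a downstream share of 56.7% (exact 95% interval 50.4 to 62.9) against 49.3% among unchanged pairs (exact binomial p = 0.0202, two-sided). This difference was not past the threshold with only the 6 libraries in the fit (share 53.5%, exact binomial p = 0.381), under the rule of 15 points in all 9 pairs of libraries (55.5%, p = 0.161) or without wild-type replicate 2 (56.2%, p = 0.05). At 3′ splice sites, use of the upstream site rose at 5 pairs and fell at 18, whereas under the rule of 15 points it was higher at 7 and lower at 7. It was listed at 99.9% in every wild-type library and 0.1% in every H765G library at chromosome II 6590087 and 6590097. In H765L the same site was listed at 50%, 66.67% and 0.1%, values that a few reads can give, and read numbers are unknown. Upstream use fell from 99.9% to 50.5% ± 6.37 at chromosome III 4660377 and 4660425, and to 58.3% ± 14.4 at chromosome III 9044090 and 9044083. At the last pair most single-library omissions ended the call.

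Among 1437 annotated events, 191 changed in H765G, and 96 of these were among the 382 tested introns, 94 up and 2 down. The mean retained share over the tested introns was 38.9% ± 1.34 per library against 29.6% ± 0.49 in wild type, a difference whose exact permutation test over 3 against 3 libraries cannot give a p below 0.1. The intron at chromosome V 6441294 to 6441336 went from 5.34% ± 5.06 to 77.4% ± 11.3 retained (adjusted p = 2.61e-05 by limma), and the intron at chromosome IV 1595511 to 1595569 from 0.1% to 68.7% ± 8.71. The intron at chromosome V 4069782 to 4069836 went from 29.6% ± 18.02 to 94.4% ± 9.57, a call that ended without wild-type replicate 1. Retention changed at 49 of 252 introns that share no end with a listed pair of alternative sites, all upward, and at 47 of 130 that do. Skipped exons changed at 38 of 430 events, with inclusion higher at 16 and lower at 22, and at 24 events without H765G replicate 2. The count was 13 at a minimum of 20 points and 3 under the rule of 15 points. With only the 6 libraries in the fit it was 20, with inclusion higher at 4 and lower at 16. Inclusion of the exon at chromosome X 9555742 to 9556296 fell from 69.2% ± 6 to 39.2% ± 2.42. The exons at chromosome III 2746383 to 2746422 and chromosome X 6845495 to 6845572 lost their call under several settings.

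**Figure D2:**
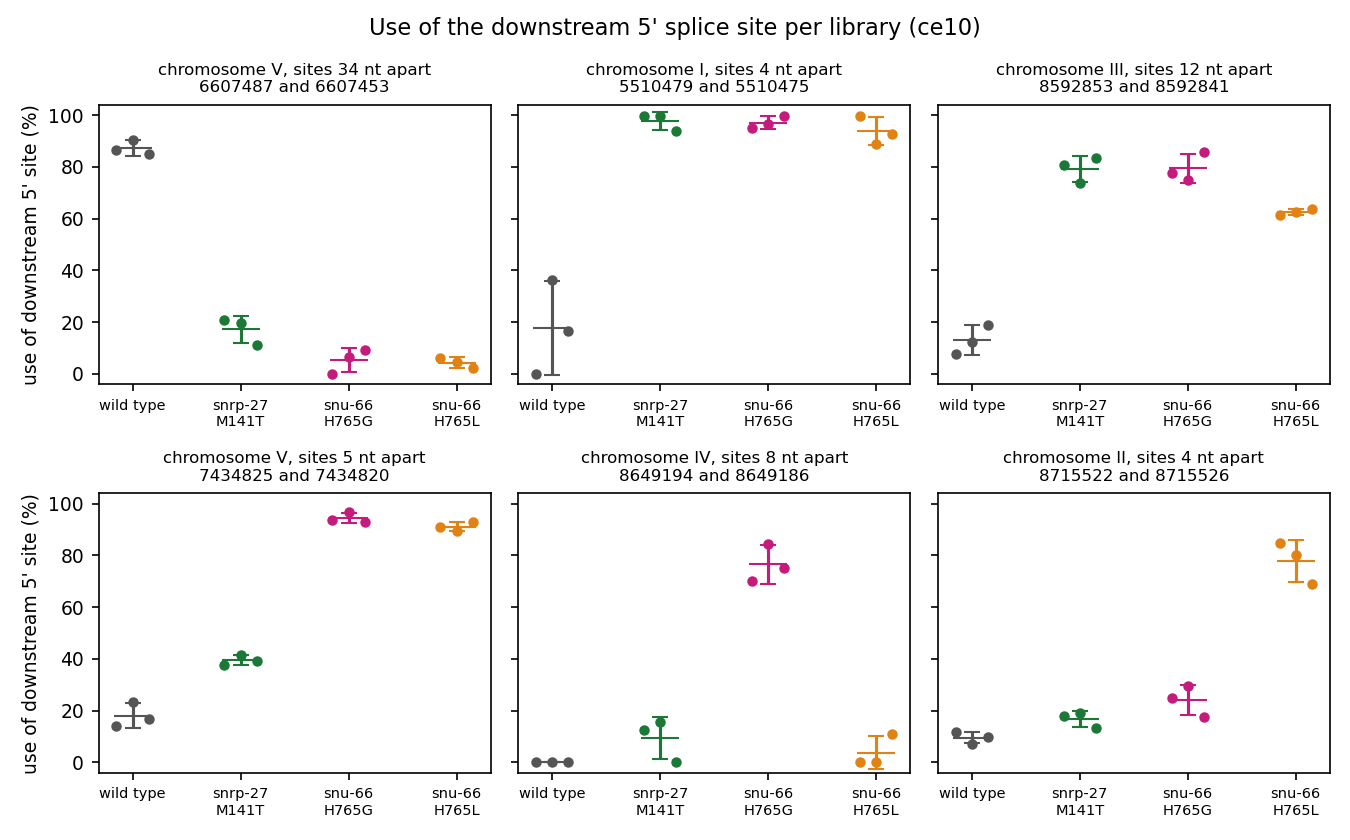
Percent use of the downstream 5′ splice site at 6 pairs, by group. Points are the 3 libraries of a group, the horizontal mark is their mean and the bar 1 SD. The chromosome V pair 34 nt apart falls from 87.4% in wild type in all 3 mutants, whereas the chromosome IV pair reaches 76.5% in H765G and the chromosome II pair 77.96% in H765L.

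The mutant with leucine at the same residue (H765L) differed from wild type at 231 of 1553 pairs of 5′ splice sites and 50 of 1858 pairs of 3′ splice sites, and the retained share was higher at 44 introns. The downstream site at chromosome II 8715526, 4 nt from 8715522, rose from 9.59% ± 2.27 to 77.96% ± 8.04 (SD, n = 3 each). At chromosome V 2211772 and 2211768, also 4 nt apart, it rose from 1.61% ± 2.61 to 67.5% ± 8.47. At the chromosome V pair 6607487 and 6607453 it dropped from 87.4% ± 2.95 to 4.33% ± 2.07, with a standard error of 3.25 points on the difference (limma adjusted p = 7.22e-07).

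Use of the downstream site rose at chromosome IV 4435577 and 4435596 from 0.1% to 99.9%, the values listed for all 3 libraries of each group. It rose from 20.5% ± 18.9 to 93.7% ± 0.22 at chromosome III 896128 and 896132, from 18.1% ± 4.76 to 91.2% ± 1.72 at chromosome V 7434825 and 7434820, by 83.3 points at chromosome V 19431032 and 19430990, and by 76.2 points at chromosome I 5510479 and 5510475. It fell from 95.7% ± 3.53 to 19.5% ± 6.39 at chromosome I 8019653 and 8019658, from 99.9% to 34.1% ± 4.05 at chromosome II 10531239 and 10531249, and from 90.8% ± 15.7 to 18.1% ± 20.2 at chromosome III 8792092 and 8792125. The pair at chromosome IV 4758479 and 4758474, which went from 83.3% ± 28.8 to 8.40% ± 14.4, lost its call with only the 6 libraries of this comparison in the fit and when any of 4 single libraries was left out, and the other 11 of the 12 pairs kept theirs under every alternative setting.

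Pairs of 5′ splice sites were 82.2% of the changed events in the first catalogue (odds ratio 6.32, Fisher's exact test, two-sided, p = 1.06e-39), with 118 moving downstream and 113 upstream. The share called was 14.9% of tested 5′ pairs and 12.8% of tested introns. The downstream share of 51.1% (exact 95% interval 44.4 to 57.7) stood against 48.7% of unchanged pairs (exact binomial p = 0.511, two-sided). At 3′ splice sites, use of the upstream site rose at 39 pairs and fell at 11, and 84, 31 and 30 pairs were called without wild-type replicates 1, 2 and 3. The largest were chromosome V 9164447 and 9164411 (23.4% ± 25.12 to 88.8% ± 19.2), chromosome II 6590087 and 6590097 (99.9% to 38.9% ± 34.6) and chromosome III 5448083 and 5448074 (27.6% ± 16.15 to 69.1% ± 9.57), and each lost its call under at least 1 alternative setting. Of 1437 annotated events 102 changed, with the retained share higher at 44 introns and lower at 5, and exon inclusion higher at 4 and lower at 13. Changed exons numbered 9 and 5 without wild-type replicates 2 and 3, and 6, 9 and 11 without H765L replicates 1, 2 and 3, against 17. The direction at exons did not hold, with 10 higher and 9 lower without wild-type replicate 1. It was 3 and 3 without H765L replicate 1, and 6 and 5 without H765L replicate 3. The other single-library omissions had more exons lower than higher. The mean retained share over tested introns was 35.6% ± 0.57. The intron at chromosome IV 1595511 to 1595569 reached 54.8% ± 18.5 retained, the intron at chromosome I 6477333 to 6477387 went from 7.22% ± 11.09 to 54.4% ± 1.39, and the intron at chromosome III 5704576 to 5704662 from 38.1% ± 10.1 to 83.0% ± 3.03. Retention changed at 18 of 252 introns that share no end with a listed pair of alternative sites and at 31 of 130 that do. Without wild-type replicate 1 the odds ratio was 3.01, and without wild-type replicate 2 or 3 the annotated count was 65.

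**Figure D3:**
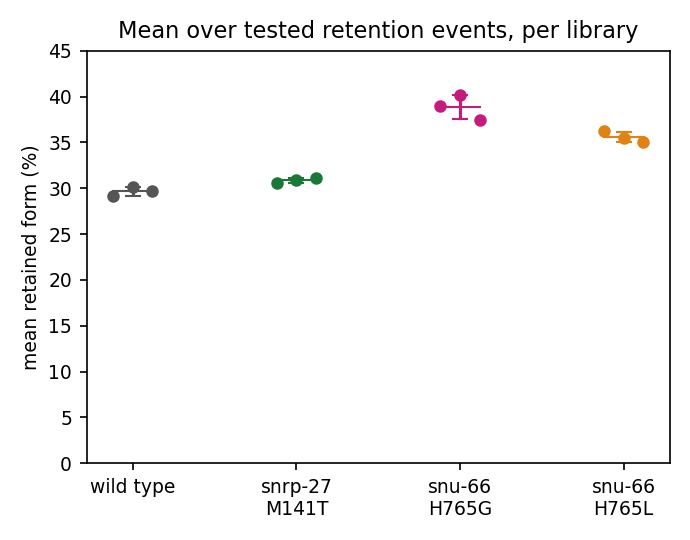
Mean percent of the retained form over the 382 tested retention events, by group. Points are the 3 libraries of each group, the horizontal mark is their mean and the bar 1 SD. H765G libraries average 38.9% and H765L libraries 35.6%, above the 29.6% of wild type and 30.9% of M141T.

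The 2 substitutions of the SNU-66 histidine differed from each other at 111 pairs of 5′ splice sites, 67 with more and 44 with less downstream use in H765G, and at 69 pairs of 3′ splice sites. The chromosome IV pair 8649194 and 8649186 had 76.5% ± 7.43 downstream use in H765G and 3.77% ± 6.36 in H765L (SD, n = 3 each, limma adjusted p = 6.6e-05). The reverse held at chromosome II 8715522 and 8715526, with 24.05% ± 5.89 in H765G and 77.96% ± 8.04 in H765L, and at chromosome III 896128 and 896132, with 43% ± 5.47 and 93.7% ± 0.22, a call that ended on the logit scale. Downstream use was 0.1% in H765G and 83.3% ± 28.8 in H765L at chromosome I 6499484 and 6499509, and 99.9% against 27.8% ± 25.4 at chromosome V 8471135 and 8471094, and both lost their call when any of 5 single libraries was left out. Use of the upstream 3′ splice site was lower in H765G at 67 of the 69 changed pairs, including chromosome III 5448083 and 5448074, with 3.77% ± 6.36 against 69.1% ± 9.57. Calls at 3′ sites depended on single libraries, with 24, 26 and 29 pairs without H765G replicates 1, 2 and 3. There were 31, 58 and 35 without H765L replicates 1, 2 and 3. The 3′ count also moved with the fit, to 94 with only these 6 libraries, 89 on the logit scale and 45 with no minimum use. By contrast, 80 to 101 pairs of 5′ sites were called when single libraries were left out. The retained share was higher in H765G at 31 of 32 changed introns, and 19 introns were called without H765L replicate 3. Between 113 and 155 events of the first catalogue were called when single libraries were left out, against 180, and the count was 114 without H765G replicate 1, 113 without H765G replicate 2, 118 without H765L replicate 1 and 115 without H765L replicate 3.

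Between the M141T and H765G mutants, 220 pairs of 5′ splice sites differed, 71 with more and 149 with less downstream use in M141T. The chromosome III pair 8792092 and 8792125 had 91.6% ± 14.4 downstream use in M141T and 15.03% ± 13.2 in H765G (SD, n = 3 each, limma adjusted p = 0.00407). The largest difference was at chromosome IV 6275323 and 6275306, with 7.68% ± 7.86 and 91.6% ± 14.4. At chromosome IV 4758479 and 4758474 the values were 83.3% ± 28.8 and 0.1%. The pairs at chromosome IV 4564320 and 4564363 and chromosome V 19431032 and 19430990 lost their call with only these 6 libraries in the fit. The chromosome V pair also lost it under the rule of 15 points and without M141T replicate 3, H765G replicate 1 or H765G replicate 2. Use of the upstream 3′ splice site was higher in M141T at 76 of 80 changed pairs. That count moved with every library left out, to 133, 51 and 51 without M141T replicates 1, 2 and 3 and to 33, 35 and 39 without H765G replicates 1, 2 and 3. The retained share was lower in M141T at 82 of 83 changed introns, such as chromosome V 6441294 to 6441336, with 8.67% ± 2.93 against 77.4% ± 11.3. Without H765G replicate 1, 197 events of the first catalogue were called against 300.

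Across the 3 mutants, 408 pairs of 5′ splice sites changed in at least 1 and 73 in all 3, of which 72 moved in the same direction. H765G and H765L shared 135 changed pairs, every one in the same direction, where independent lists would share 18.9 pairs in the same direction. Simulated unchanged mutants against the same wild-type libraries shared 0.05 on average, a value that is near 0 because hardly any of their pairs were called, so it gives no baseline for lists of this length. M141T shared 90 pairs in direction with H765G (14.1 in direction for independent lists, 0.03 simulated) and 93 with H765L (13 and 0.02). Over all 1553 tested pairs, the differences from wild type correlated at r = 0.75 between the SNU-66 alleles (0.496 simulated) and at 0.58 between M141T and each of them (0.50 and 0.502 simulated). These correlations are across events, which are not independent. The covariance exceeded the simulated one by 209.2 squared points for the SNU-66 alleles, by 131.1 for M141T with H765G and by 125.5 for M141T with H765L. Part of the excess overlap may come from the shared wild-type libraries, since 3 cannot be split with 2 in each part.

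The median distance between the sites of changed pairs was within 1 nt of that of unchanged pairs. It was 12 nt in changed against 11 nt in unchanged pairs for M141T (permutation p = 0.709, two-sided), 10 against 11 nt for H765G (permutation p = 0.657) and 11 against 11 nt for H765L (permutation p = 1). Pairs up to 30 nt apart were 86.9%, 83.9% and 85.7% of the changed pairs in these mutants, against 82.3%, 82.6% and 82.3% of the unchanged pairs. Direction among changed pairs did vary with distance, in groupings by distance chosen after the values were seen. A site with low use in wild type has more room to rise, and a site with high use more room to fall. Wild-type use was not matched between distances. The tests below therefore do not separate an effect of distance from which site wild type used more at each distance. Of the changed pairs exactly 4 nt apart, 41 moved downstream and 7 upstream in H765G, where pairs at other distances moved downstream as often as upstream (odds ratio 5.86, Fisher's exact p = 4.22e-06). In H765L 32 moved downstream and 8 upstream, against 86 and 105 (odds ratio 4.88, Fisher's exact p = 4.99e-05), and in M141T 12 and 7, against 64 and 92 (odds ratio 2.46, Fisher's exact p = 0.0863). Those 19 pairs in M141T were 12 without wild-type replicate 3, with 6 in each direction, and 11 without mutant replicate 2. All changed pairs at most 3 nt apart moved upstream, 12 in M141T, 9 in H765G and 15 in H765L.

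**Figure D4:**
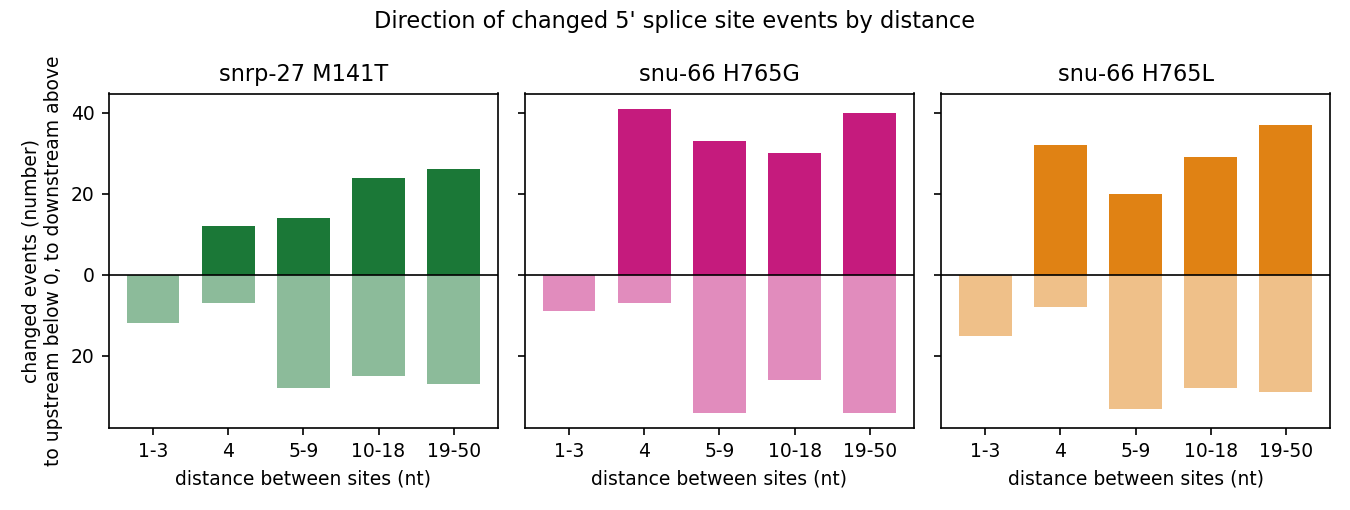
Numbers of changed 5′ splice site pairs by distance between the sites in nt, for each mutant against wild type. Bars above 0 count pairs that moved to the downstream site and pale bars below 0 pairs that moved to the upstream site. At 4 nt, 41 pairs in H765G and 32 in H765L moved downstream.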

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

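The tests in this part were chosen after the results were seen, except the test of retention at introns that share no end with alternative site pairs, for which the values that would count for and against the explanation were set before its result was seen.

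The alleles of SNU-66 differed directly at 69 pairs of 3′ splice sites, and the upstream site was used less in H765G at 67 of them, but only 24, 26 and 29 pairs were called without H765G replicates 1, 2 and 3 and 31 and 35 without H765L replicates 1 and 3, with less use in H765G at 23 to 33 of them. Over 1127 pairs 4 to 9 nt apart, mean upstream use per library was 29.04% ± 0.16 in H765G, 33.9% ± 0.11 in H765L, 33.7% ± 2.02 in M141T and 30.8% ± 1.65 in wild type (SD, n = 3 each), where wild-type libraries ranged from 29.7% to 32.7%. A difference in depth could move values off 0% and 100% and so give a direction, and with 39.8% ± 2.09 of 3′ pairs in H765G and 35.9% ± 3.34 in H765L within 0.15 points of these ends, the 31.2% of 1858 tested pairs that were higher in H765G does not decide on depth. A difference in stage or tissue make-up between cultures may also move 3′ splice sites, and wild-type libraries should then vary along the same axis. Across 3′ pairs, wild-type replicates 1, 2 and 3, each minus the mean of the other wild-type libraries, were correlated with H765L minus H765G. The values of r were 0.17, -0.04 and -0.14 (0.04, -0.03 and -0.01 across 5′ pairs), too weak to decide. Depth, culture, other differences between the strains and an effect of the substitutions all stay open.

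Retention differed directly between M141T and H765G at 83 introns, with 82 higher in H765G. Use of another splice site of the same intron could lower the spliced form without more retention. Under 5% called was the cut-off set for that cause among introns that share no end with a listed pair of alternative sites. Of the 252 such introns tested, 16.7% were called, all higher in H765G. Listed pairs, at most 50 nt apart, therefore do not account for these calls, but a site farther away or unlisted could. Among the 130 introns that share an end, 31.5% were called, and for them use of a listed site stays open. Unspliced RNA or genomic DNA in the H765G libraries could raise retention in most introns by amounts that depend on transcript level. The median difference from wild type was 4.16 points over all 382 introns, and without transcript levels it cannot be told apart from an effect of H765G.

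Other splits of the 6 libraries of each comparison into 3 and 3 were fitted with only those libraries. In all 5 comparisons and both catalogues, only 1 of the 10 splits, the real one itself, reached the real number of changed events, and 10 splits are too few for a share under 0.05. Every other split mixes both groups in each part. Any difference between the groups, whatever its cause, then widens the spread within parts and lowers the count. In the library-intron catalogue the real split called 101 events for M141T against wild type (highest other split 1), 206 for H765G (1), 191 for H765L (3), 174 between H765G and H765L (2) and 209 between M141T and H765G (2). For 5′ splice site pairs alone the numbers were 97 (1), 187 (0), 167 (1), 80 (2) and 147 (1). For annotated events the real splits called between 5 (M141T against wild type) and 135 (H765G against wild type), and every other split called 0.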

How the results depend on the processing

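The excess of 5′ over 3′ pairs among changed events of the first catalogue kept its direction and side of the threshold in every alternative. Its odds ratio ranged from 4.24 to 30.9 in M141T, 12.6 to 29.2 in H765G and 3.01 to 12.5 in H765L. The logit scale, limma's options, other minimum uses, missing libraries and 1 event per set sharing an intron were added after the data were seen, as were all alternatives for counts of 3′ pairs and introns and the minimum of 5 points for the share and direction of 5′ pairs. Requiring 15 points in all 9 pairs of libraries gave 123, 178, 158 and 102 changed events for M141T, H765G and H765L against wild type and H765G against H765L, and 1.4e+02 (rounded) for M141T against H765G, with 113, 164, 143, 61 and 106 pairs of 5′ sites in these 5 comparisons, and 7, 66 and 39 annotated events in the mutants. Requiring 20 points gave 182 changed events in H765G, 179 in H765L, 90 between the alleles and 158 between M141T and H765G, 58 and 117 pairs of 5′ sites in these comparisons of mutants, and 7, 86 and 40 annotated events. The minimum of 20 points passes fewer events by construction. The rule of 15 points does not, since it sets no threshold on p, and in every comparison it passed events that were not called at 10 points, with for example 133 of its 158 in H765L and 69 of its 102 between the alleles called there, and the cause was not tested. With only the libraries compared, M141T had 101 changed events, 97 pairs of 5′ sites and 5 annotated events, and the cause was not tested. The downstream share in M141T, 43.4% against 43% of unchanged pairs, fell on the other side of the unchanged share with only the libraries compared (33%), on the logit scale (40.8%), with robust and trend options (42.3%), with a minimum use of 5 percent (44.2%), with up to 1 missing library per group (43.1%), with 1 event per set (41.9%), with a minimum of 5 points (42.2%) and with the rule of 15 points (41.6%), and the cause was not tested. The downstream share in H765G was not past the threshold with only the libraries compared (53.5%) or the rule of 15 points (55.5%), and the cause was not tested. In M141T, H765G and H765L against wild type, between the alleles and between M141T and H765G, in this order, changed 3′ pairs numbered 9, 8, 20, 32 and 41 at 20 points and 10, 14, 15, 41 and 35 under the rule of 15 points, and changed introns 5, 59, 27, 6 and 49 at 20 points and 5, 50, 26, 3 and 38 under that rule. With no minimum use there were 13 changed 3′ pairs in M141T and 45 between the alleles, and with only the libraries compared 4 in M141T and 24 in H765L. Changed introns numbered 3 in M141T and 17 between the alleles with only the libraries compared, and 19 between the alleles on the logit scale, and the cause was not tested. Leaving out single libraries gave 12 to 47 changed 3′ pairs in M141T, 30 to 84 in H765L, 24 to 58 between the alleles and 33 to 133 between M141T and H765G, 4 to 8 changed introns in M141T and 19 to 29 between the alleles, 113 to 155 changed events between the alleles, 197 to 339 between M141T and H765G, 7 to 13 annotated events in M141T and 65 to 101 in H765L, and downstream shares of 41.6% to 45.8% in M141T and 56.2% to 60.3% in H765G. Of 110 named features and comparisons, 58 kept their call under every alternative, 52 lost it under at least 1 and 0 reversed. Not run were count models, read filters, gene counts and 1 event per gene, for want of counts and gene names. No paired analysis was possible because replicate numbers only name libraries. Depth is unknown, which limits every value, those with an SD of 0 included.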

Other observations

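The tests in this part were chosen after the results were seen. Pairs of 5′ splice sites a multiple of 3 nt apart were 52% of changed pairs in M141T against 38.2% of unchanged pairs (odds ratio 1.75, Fisher's exact p = 0.000548). In H765L they were 46.8% against 38.5% (odds ratio 1.40, Fisher's exact p = 0.0197) and in H765G 43.7% against 39% (odds ratio 1.22, Fisher's exact p = 0.161), without adjustment over the 3 mutants. At pairs 4 nt apart, M141T and H765G differed directly at 42, with downstream use lower in M141T at 37 and higher at 5. Of the 220 pairs that differed in all, those at other distances were higher in M141T at 66 and lower at the rest, so lower use was the more frequent direction there too (odds ratio 0.23, Fisher's exact p = 0.00156). Between H765G and H765L, 19 pairs at 4 nt were higher in H765G and 10 lower, against 48 and 34 (Fisher's exact p = 0.659). Wild-type use was not matched between distances in these comparisons of mutants either. Mutually exclusive and multiple skipped exons also changed in H765G, at 7 of 58 and 14 of 84 events, and 12 of those 14 had lower inclusion. The 14 events overlap and form only 7 sets that share no intron, and the 7 mutually exclusive events form 6. Of the latter type, 4 were called without wild-type replicate 3 and 3 without H765G replicate 3. At a minimum of 20 points 2 mutually exclusive and 3 multiple skipped events were called. Under the rule of 15 points these numbers were 0 and 2.

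Fewer pairs of 5′ splice sites were listed within 0.15 points of 0% or 100% in the mutants, 42.5% ± 0.87 in M141T, 40.7% ± 0.74 in H765G and 43.7% ± 3.69 in H765L against 53.6% ± 1.28 in wild type (SD, n = 3 each). Deeper sequencing of the mutants could give such a pattern, and would then lower the shares of 3′ splice sites too. For these the shares were 35.02% ± 2.29, 39.8% ± 2.09, 35.9% ± 3.34 and 41.8% ± 3.75. The gap between 5′ and 3′ pairs was 10.2 to 14.7 points in 3 wild-type libraries and -1.44 to 8.87 in 9 mutant libraries. The exact permutation p of 0.00909 (two-sided) treats the 12 libraries as exchangeable, although the 9 come from 3 strains. A gap in points also narrows if depth lowers both shares in proportion, so depth stays open in M141T and H765L. In H765G the 3′ share was 37.98% to 42.08% per library, within the 37.51% to 44.66% of wild type, while the 5′ share fell. The 3′ share can gauge depth only if 3′ use itself did not change in H765G. Upstream use was above wild type at only 37.2% of the 1858 tested 3′ pairs, so depth stays open in H765G too. Use of more 5′ splice sites in each mutant remains a hypothesis from the same data. A pair with a site used only in mutants can be listed because of the mutants. Such a pair stands near 0% or 100% in wild type by the way it was listed.

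Events listed in all 9 libraries of the other groups and in none of the group's own numbered 9 for wild type, 6 for M141T, 4 for H765G and 5 for H765L, of which 8, 2, 4 and 3 were 5′ splice site pairs.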
